A study of Xenopus tropicalis with 8 samples.

How the data were processed

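The data were single-cell RNA sequencing counts from Xenopus tropicalis tadpoles of a pax6:GFP line, in which cells with GFP signal were sorted from dissociated tail or trunk tissue. Per the labels, 8 samples were made, 1 for each of 8 groups: tail tip and mid-trunk at day 0 (stage 41, from the same animals), and uninjured and injured tails at days 1, 3 and 7. Each sample pooled 22 to 294 tadpoles, aimed at 10000 cells and was prepared with a 10x GEM-X 3' v4 kit. Live singlets were sorted, and the gate was drawn to leave out most autofluorescent cells.

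The deposited values were counts of unique molecular identifiers (UMIs), whole numbers per gene and barcode in 1 matrix of 22107 genes and 41631 barcodes. The matrix was made with Cell Ranger 9.01 and Seurat 3.1 was also used, per the submitters' processing notes, and the header of the matrix gave Cell Ranger 9.0.1. The genome build, the gene annotation, the cell calling settings and any depth normalization in the aggregation were not given in the sources used here, so no gene positions are printed. Gene identity is the Ensembl identifier and symbol of the deposited gene table, in which 6916 features had an identifier in place of a symbol. Barcodes carried a suffix from 1 to 8, which marks the library. No file or label tied a suffix to a sample, so 41631 of 41631 barcodes had no known sample. The libraries are therefore called library 1 to library 8 by suffix, with no condition, and their values are given one by one or as a range and median.

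Barcodes with under 500 detected genes (8433) and those with over 15% mitochondrial counts (3186, from 13 mitochondrial genes) were left out. Doublets were scored per library with simulated sums of 2 cells (2 simulated per observed cell) and up to 50 neighbours per observed cell. An automatic threshold on that score was tried at the start and called between 0.248% and 96.1% of a library's cells, so it was replaced, after the data were seen, by the highest scores up to a nominal rate of 0.4% per 1000 barcodes. This removed 906 of 30012 cells (3.02%) and left 29106. Clustering used 2000 variable genes (variance of negative binomial Pearson residuals, overdispersion parameter 100), 30 principal components of log values per 10000 counts, 20 neighbours and the Leiden method at resolution 1, without any alignment of the libraries. Mitochondrial genes and every gene of the 15 reported lists, pax6 included, were left out of the clustering genes. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-image 0.26.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.

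Clusters were named from 32 fixed marker lists. A class needed a mean log2 ratio of at least 1 over the median cluster (with 5 CPM added to both sides), at least 3 markers raised at 20 CPM or more, and a margin of 0.25 over the next class. A cluster stayed unnamed when its 10 leading genes held more markers of another class, or when its median UMI count times 3 stayed below that of its libraries and no leading gene was its own marker. The thresholds, the use of the median cluster, the joint class of neural progenitor and ependymal markers, the addition of myosin genes to the check of leading genes and the thinning depth of 1000 UMIs were set after the data were seen. Names carry the suffix -like, because the submitters' own cell annotation was not used here. Progenitor-like and neuron-like cells were then clustered again among themselves with the same steps, where markers of other neural classes, floor and roof plate included, counted as those of another class only if that class was among the names on offer.

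The gene lists, cell filter, comparisons, thresholds of fold and abundance, rule for named genes and the settings to vary were fixed before the data were examined. No group had replicates, and neither cells nor the 8 libraries, whose samples are unknown, were used as replicates, so no test gave a p-value. Genes were compared between progenitor-like and neuron-like cells by the ratio of their CPM, summed counts scaled to the class total. A gene passed at 4-fold or more, with 20 CPM or more in the higher class and the same direction in each library with at least 50 cells of both classes; genes used for clustering were left out. A class with fewer than 3 counts was set to 3 counts for this ratio. Shares of cells with a UMI were measured after each cell was thinned to 1000 UMIs, and shallower cells were left out there. Shares have 95% exact (Clopper-Pearson) binomial intervals, and a count of 0 allows up to 3 counts. Intervals and limits cover counting error only, not variation between animals. The median ratio of each list was ranked among 10000 random gene lists of the same size and similar mean CPM, drawn from the tested genes. Those exclude the clustering genes, whereas list genes were kept out of clustering whatever their variance. This favours extreme percentiles for the lists. The named genes were pax6, the 12 largest folds in each direction among genes with a symbol that passed, up to 6 members of each list with the largest fold, and the fixed markers, transmitter and neuropeptide genes of each neuron-like sub-cluster. The gene comparison was tested on simulated data with counting noise alone: 0 of 5871 unchanged genes and 0 of 52 genes at 2-fold were called, against 22 of 49 at 4-fold, 43 of 43 at 8-fold and 56 of 56 at 16-fold.

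The settings varied were a filter of 1000 genes, doublets kept, resolutions 0.5 and 2.0, 4000 variable genes, 15 principal components, reported lists kept among the clustering genes, no thinning, at least 2 pax6 UMIs, other abundance and fold thresholds, each library left out in turn, and the unweighted mean over libraries. Added after the data were seen were gad1.1 and gad1.2 as GABAergic genes, a single slc17a6 feature, neuron-like cells without a cluster led by photoreceptor genes, cells of at least 3000 UMIs, markers scored against all other cells, and no naming margin. Lists of lens and photoreceptor genes were also written after the leading genes of clusters had been seen.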

Results

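Messenger RNA of single cells was counted in 8 samples of tail or trunk from tadpoles of a line in which GFP follows pax6, a transcription factor gene of neural progenitors. The series asks how the cut spinal cord restores its range of neurons. Of the 8 groups, each held 1 sample, and the 8 deposited libraries could not be matched to them. The libraries held 4209983 (library 6) to 75104565 (library 7) UMIs, with 34571128 in library 1, 10424868 in library 2, 39498786 in library 3, 58635626 in library 4, 31819598 in library 5 and 21034319 in library 8. After filtering, 384 (library 6) to 8683 (library 7) cells per library were used, 29106 in all, with a median of 5472.5 UMIs and 2080.5 genes per cell. The lowest median depth was 2790.5 UMIs per cell in library 3 and the highest 9367.5 in library 4. There were no replicates.

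The question of which cells passed the sort was answered by cluster names. Neural classes made up 24.5% of the 29106 cells (7118 cells, 95% exact interval 23.96% to 24.95%). They were progenitor-like cells, a joint class of neural progenitors and ependymal cells, with sox2, sox3, sox9 and hes5 genes, markers of neural stem cells, and with cilium genes such as dnah5 and cfap45 among the leading genes of their clusters (3125 cells, 10.7%), neuron-like cells with elavl3, snap25 and stmn2, genes of the neuronal RNA-binding, synaptic and cytoskeletal machinery (3230 cells, 11.1%), and precursor-like cells with the neurogenic factors neurog1, neurod1 and neurod4 (763 cells, 2.62%). The most abundant other classes were mesenchyme-like cells with collagen genes such as col1a1 (6351 cells, 21.8%), skeletal muscle-like cells (5182 cells, 17.8%) and notochord-like cells with tbxt, the notochord factor brachyury (1889 cells, 6.49%). Myeloid-like cells made up 3.17%, melanocyte-like cells 2.87%, secretory epidermis-like cells 1.90%, epidermis-like cells 0.759%, erythroid-like cells 0.752%, endothelial-like cells 0.649% and multiciliated cells 0.144% (0.0747% without library 1). Another 5585 cells (19.2%) in 7 clusters stayed unnamed, with a median of 1511 UMIs. This share was 11.5% with at least 1000 genes, 8.78% from 3000 UMIs, 31.7% at resolution 0.5 and 44.5% with markers scored against all other cells.

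Across the 8 libraries the neural share ran from 15.2% in library 4 to 44.3% in library 2, with a median of 31.4%. Neuron-like cells made up 26.8% of the neural cells of library 3 and 60.1% of those of library 5, with a median of 48.8%, against 45.4% with all cells pooled. The mesenchyme-like share ran from 2.60% in library 6 to 26.6% in library 7, and the muscle-like share from 3.33% in library 2 to 34.8% in library 4. Epidermis-like cells reached 29.2% in library 6, and without that library their pooled share was 0.3795%. Unnamed clusters 6 (1255 cells) and 9 (972 cells) also had the epidermis markers cdh1, dsp, epcam and grhl3 raised, with 304 and 398 cells in library 3. The naming rule left them out, so the epidermis-like shares may be too low outside library 6. Erythroid-like cells reached 3.35% in library 3, and their pooled share without it was 0.291%. Shares of the smaller classes moved by over 1.5 times with other clustering or naming settings, such as 3.14% epidermis-like and 0.227% melanocyte-like cells at resolution 2.0. The notochord-like share was 3.14% with 4000 variable genes, the mesenchyme-like share 13.7% at resolution 0.5, and with markers scored against all other cells the mesenchyme-like share was 10.2% and the muscle-like share 4.09%.

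**Figure D1:**
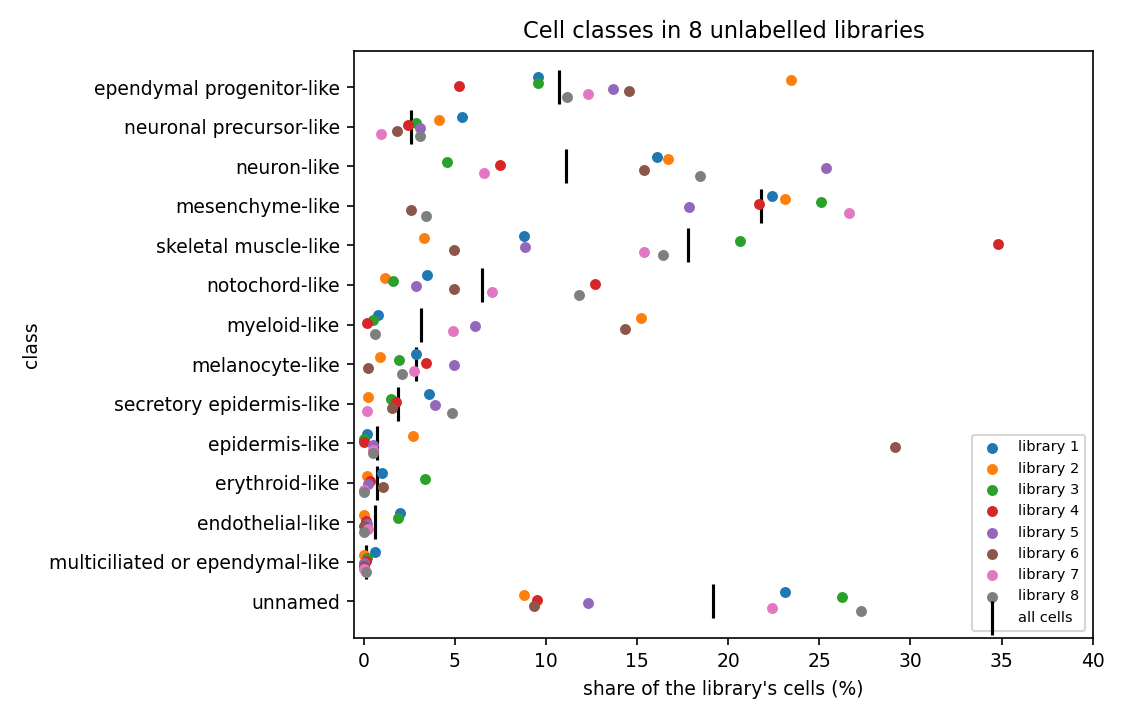
Share of each library's cells in percent (x axis) for each cell class (y axis), with 1 coloured point per unlabelled library and a black bar for all cells pooled. Progenitor-like cells run from 5.26% to 23.5% and neuron-like cells from 4.56% to 25.4% of a library.

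Pax6 (ENSXETG00000008175), the gene whose reporter was used for sorting, stood at 113 CPM (counts scaled to the class total) in progenitor-like cells, 99.4 CPM in precursor-like cells, 16.7 CPM in neuron-like cells and 0.980 CPM in the named non-neural cells. After thinning to 1000 UMIs, 286 of 2876 progenitor-like cells (9.94%, 95% exact interval 8.87% to 11.1%) and 9.81% of precursor-like cells (7.74% to 12.2%) had a pax6 UMI. The shares were 0.912% (0.602% to 1.32%) in neuron-like cells and 0.197% (0.134% to 0.280%) in named non-neural cells, whose median depths before thinning were 4017.5 and 9000 UMIs, against 5003 UMIs in progenitor-like cells. The neuron-like level rested on library 1, where it was 88.8 CPM, and without that library it was 3.52 CPM with a share of 0.289%. Sub-cluster 22 of the neuron-like cells, 47 cells that all came from library 1, had 1205 CPM of pax6, against at most 35.2 CPM in any other sub-cluster. The ratio of progenitor-like to neuron-like cells was 6.74-fold with all libraries and 25.8-fold without library 1. In progenitor-like cells the share per library ran from 5.38% (3.40% to 8.03%) in library 5 to 22.8% (18.3% to 27.8%) in library 1, with a median of 8.54%. Progenitor-like cells of library 1 had 314 CPM of pax6, and without that library the class level was 90.6 CPM. Of the 352 progenitor-like cells of library 1, 201 lay in unnamed sub-cluster 3 of that class, which had 460 CPM.

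Genes of the cell cycle stood high in progenitor-like cells: mki67, a marker of dividing cells, at 248 against 21.3 CPM in neuron-like cells, and top2a, the topoisomerase of dividing chromosomes, at 211 against 11.2 CPM. At least 2 UMIs of the G2/M genes were found in 51.6% of thinned progenitor-like cells (49.8% to 53.4%), 32.2% of precursor-like cells (28.8% to 35.7%) and 10.1% of neuron-like cells (9.07% to 11.3%), the last being the class set beforehand for comparison. Without thinning the shares were 82.7% in progenitor-like and 55.6% in neuron-like cells. Among thinned cells of other classes, the shares were 17.5% in skeletal muscle-like, 48.6% in mesenchyme-like and 69.5% in erythroid-like cells. The progenitor-like share per library ran from 25.2% (19.9% to 31.1%) in library 2 to 65.8% (60.7% to 70.6%) in library 3, with a median of 47.6%. Of the 35 measured G2/M genes, 33 were at least 4-fold higher in progenitor-like cells and 0 in neuron-like cells (median log2 ratio 4.23), with anln (ENSXETG00000039411), a cytokinesis protein, at 34.5-fold and cdca2 at 30.2-fold. Of 30 S phase genes, 24 were higher in progenitor-like cells by 4-fold and 0 in neuron-like cells (median 3.74), with mcm2 and mcm5, subunits of the replicative helicase, at 37.4-fold and 32.1-fold. With doublets kept, the G2/M median was 3.46.

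The comparison of progenitor-like with neuron-like cells asked which genes mark each class beyond those used to cluster them. Of 7007 genes, 841 were at least 4-fold higher in the 3125 progenitor-like cells and 793 in the 3230 neuron-like cells, each in the same direction in all 8 libraries. Among the 12 largest folds toward progenitor-like cells were genes of the motile cilium: odad2 (ENSXETG00000004553), which docks outer dynein arms, at 194.5 against 2.78 CPM (70.0-fold), cfap57 (65.3-fold), drc7 of the nexin-dynein regulatory complex (61.1-fold), cimap1a (59.2-fold), cfap100 (48.3-fold) and CROCC2 (ENSXETG00000012154), named for the ciliary rootlet (72.8-fold). The others were tmem221 (ENSXETG00000036930) at 80.8-fold, the zinc transporter gene slc39a12 at 55.3-fold, kiaa2012 at 51.2-fold, tsga10 at 50.5-fold, aadacl3 at 49.6-fold and ccdc105 at 48.6-fold.

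Among the 12 largest folds toward neuron-like cells were acetylcholine genes: the choline transporter gene slc5a7 (ENSXETG00000010384) at 266 against 0.561 CPM (475-fold), the vesicular transporter gene slc18a3 (335-fold) and chat (ENSXETG00000005624), which makes acetylcholine, at 664.6 against 2.07 CPM (321-fold). The nicotinic receptor subunit gene chrna2 stood 313-fold higher. Another subunit gene, chrnb4, had 849 against 2 UMIs (ratio 472, interval 130 to 3902), or 314.5-fold with the lower count set to 3. Vesicular glutamate transporter genes were also among them, slc17a7 at 392-fold and slc17a6 (ENSXETG00000008393) at 299.9-fold. The sodium channel subunit gene scn2b had 1080 against 3 UMIs (ratio 400.1, interval 137 to 1943) and fam135b 851 against 3 UMIs (ratio 315, interval 108 to 1532). The list was completed by crhr1.2, a receptor gene for corticotropin-releasing hormone (343-fold), eml5 (307-fold) and the epoxide hydrolase gene ephx4 (298-fold). Genes of the reported lists, such as slc5a7, slc18a3, chat, slc17a7, slc17a6 and scn2b, were never clustering genes. Other variable genes were clustering genes and so were left out of this ranking, which favours the list genes. Of these 24 folds, 12 moved by over 1.5 times with doublets kept (tmem221 to 33.8-fold), 12 with the unweighted mean over libraries (aadacl3 to 16.1-fold) and 10 at resolution 0.5 (slc5a7 to 29.5-fold). Of all 103 named genes, 40 moved by over 1.5 times with doublets kept, 24 at resolution 0.5 and 21 with the unweighted mean. Leaving out a library moved slc39a12 to 86.5-fold (library 1), slc17a7 to 606-fold (library 3), slc5a7 to 945-fold (library 8), and scn2b to 224-fold, fam135b to 188-fold and chrnb4 to 209.6-fold (library 7).

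Several genes of the Hedgehog, Wnt, Notch and matrix lists were also higher in progenitor-like cells. Of 8 Hedgehog pathway genes, 7 were at least 4-fold higher there and 0 in neuron-like cells (median log2 ratio 2.68), among them the transcription factor gene gli3 at 29.2-fold (11.5-fold with doublets kept), the signal transducer gene smo at 26.6-fold and gli1 at 14.0-fold. Of 15 Wnt pathway genes, 8 were higher and 0 lower (median 2.63), with the secreted Wnt enhancer gene rspo3 at 25.6-fold, the receptor gene fzd2 at 13.0-fold and wnt4 at 12.2-fold. In the Notch list 7 of 13 genes were higher, among them hes1 (19.5-fold, and 29.8-fold without library 5), dtx4 (10.5-fold) and hey1 (10.3-fold), while dtx1 was 24.4-fold higher in neuron-like cells (median 2.06). Of 16 regeneration and matrix genes, 12 were higher and 0 lower (median 2.98, and 2.36 with doublets kept), with the RNA-binding protein gene lin28a at 19.1-fold, the Hippo pathway co-activator gene yap1 at 18.6-fold, the hyaluronan receptor gene cd44 at 13.1-fold and fibronectin (fn1) at 13.0-fold. The leptin gene lep of that list stood at 4.01 CPM in progenitor-like and 49.4 CPM in neuron-like cells, a direction shared by 5 of 8 libraries, so it did not pass.

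Other signalling lists were mixed. Of 11 FGF pathway genes, 4 were higher in progenitor-like cells, such as the feedback inhibitor gene spry2 (13.9-fold) and the receptor gene fgfr2 (13.1-fold), and the ligand gene fgf10 was 7.53-fold higher in neuron-like cells (median 0.96). In the list of BMP and TGF-beta genes, bmp2 (10.1-fold) and id3 (12.2-fold) were higher in progenitor-like cells and id4 was 7.495-fold higher in neuron-like cells, 2 and 1 of 11 genes (median 1.56). Of 21 Hox genes, which set position along the body axis, 0 passed in either direction at 4-fold and 2 did so at 2-fold, hoxb9 at 3.09-fold (4.79-fold with 15 principal components) and hoxd13 at 3.26-fold, both toward progenitor-like cells (median 0.60). The Hox gene hoxc9 stood at 1035 CPM in progenitor-like and 551 CPM in neuron-like cells. Of 15 immediate early and stress genes, 0 passed at 4-fold and at 2-fold 5 were higher in progenitor-like cells and 1 in neuron-like cells (median 0.57), with the cytokine feedback gene socs3 at 3.22-fold and the chaperone gene dnajb1 at 2.22-fold toward neuron-like cells. Ranked among 10000 random lists, the Hox median stood at percentile 98.4, the FGF median at 97.3 and the stress gene median at 94.4. The random lists lacked the variable genes used for clustering, which favours extreme percentiles, so these ranks decide nothing.

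Neuron-like cells were higher for genes of excitability, peptides and axon growth. Of 30 genes of excitability and synaptic receptors, 28 were at least 4-fold higher in neuron-like cells and 0 lower (median log2 ratio -5.91, and -4.51 at resolution 0.5), among them glra3, a glycine receptor subunit gene (270.6-fold), gria2, an AMPA receptor subunit gene (256-fold), and cacna1a, a calcium channel gene (163-fold). All 6 measured features of the neuropeptide list passed toward neuron-like cells (median -7.11), led by tac1 (ENSXETG00000025709), the substance P precursor gene, at 2007 against 10.5 CPM (191.5-fold), and by vip at 162-fold (319-fold with at least 1000 genes and 343-fold from 3000 UMIs). The neuropeptide median was -6.41 at resolution 0.5. Of 26 axon growth genes, 12 were higher in neuron-like cells and 0 in progenitor-like cells (median -1.79), with the axonal adhesion genes cntn2 and cntn1 at 72.2-fold and 64.0-fold, the semaphorin co-receptor gene nrp2 at 21.4-fold and the guidance ligand gene slit2 at 19.1-fold. In the transmitter list 8 of 11 features were higher in neuron-like cells and 1, the glycine transporter gene slc6a9 (4.93-fold), in progenitor-like cells (median -6.59, between -4.88 at resolution 0.5 and -7.52 with the unweighted mean).

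**Figure D2:**
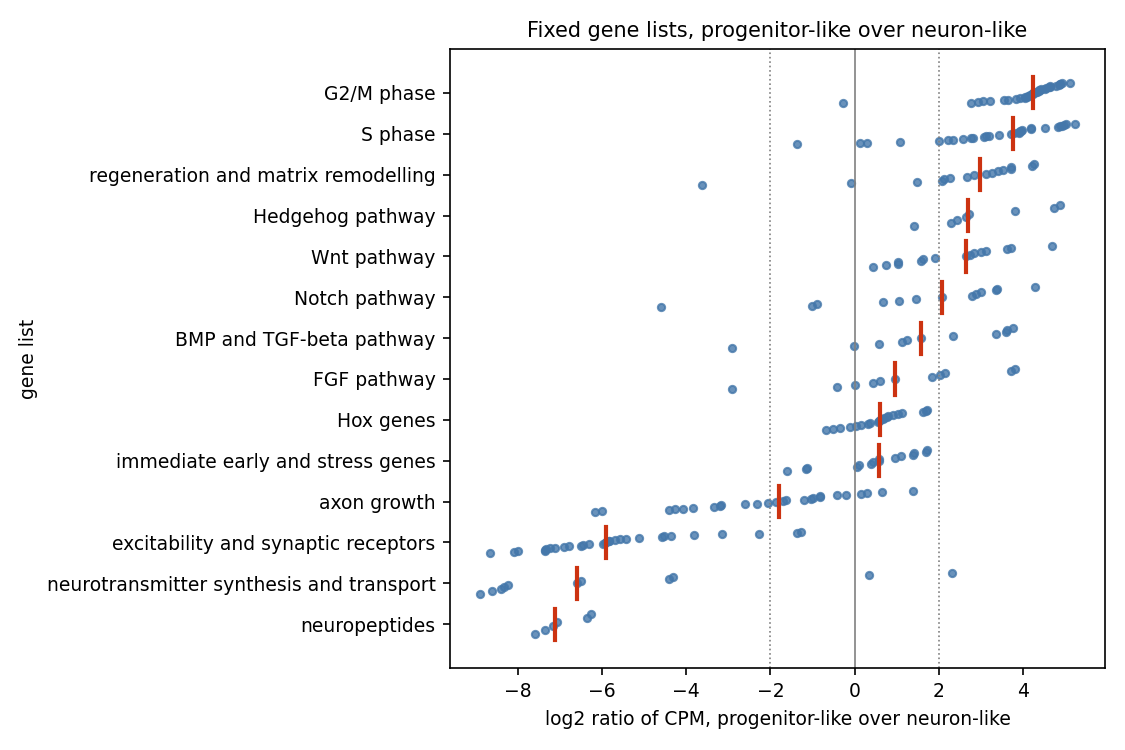
Log2 ratio of CPM in progenitor-like over neuron-like cells (x axis) for the measured genes of each fixed list (y axis), with 1 blue point per gene, a red bar at the list's median and dotted lines at 4-fold. The medians run from -7.11 for neuropeptides to 4.23 for G2/M genes.

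Transmitter genes showed which kinds of neurons the sort had kept. Of 2960 thinned neuron-like cells, 46.4% had a UMI of chat or slc18a3, the cholinergic genes (44.6% to 48.2%), against 0.452% of progenitor-like cells. Vesicular glutamate transporter genes were found in 28.5% (26.9% to 30.2%), but also in 5.84% of progenitor-like and 6.67% of mesenchyme-like cells, which should lack them. This background came from a second feature with the symbol slc17a6 (ENSXETG00000005500), present in 5.598% of progenitor-like and 3.38% of neuron-like cells; without it the shares were 26.0% (24.4% to 27.6%) and 0.278%. The GABA-synthesis gene gad2 was found in 3.78% (3.13% to 4.54%) of neuron-like cells against 0.139% of progenitor-like cells, and the symbol gad1 was not among the features. With gad1.1 and gad1.2, added after the data were seen, the GABAergic share was 7.43% (6.51% to 8.44%) against 0.243%. The glycine transporter gene slc6a5 was found in 2.30% (1.79% to 2.90%) and slc32a1, the vesicular transporter gene of both inhibitory transmitters, in 5.61% (4.81% to 6.50%), against 0.0348% and 0.174%. Glutamatergic and inhibitory genes shared a cell in 0.709% of neuron-like cells (0.440% to 1.08%). The overlap of glutamatergic with cholinergic genes was not counted per cell. In the sub-clusters below with cholinergic genes in at least 49% of cells, glutamatergic genes were found in 6.82% (sub-cluster 16) to 37.8% (sub-cluster 12). The cholinergic and glutamatergic shares therefore overlap and do not count separate kinds of neurons. Across libraries the cholinergic share ran from 36.5% to 65.4% with a median of 48.0%, and the glutamatergic from 21.1% to 37.7% with a median of 25.0%. The GABAergic share ran from 1.69% to 12.3% with a median of 3.04%. These shares rest on 57 (library 6) to 762 (library 5) thinned neuron-like cells per library, so an extreme can come from few cells. Median depths were 4017.5 UMIs in neuron-like and 5003 UMIs in progenitor-like cells before thinning. Without thinning the shares were 59.8% cholinergic, 59.6% glutamatergic, 9.20% GABAergic and 5.05% glycinergic, and the mesenchyme-like background of glutamatergic genes was 34.7%.

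Clustering the neuron-like cells again gave 24 sub-clusters, of which 7 could be named. Motor neuron-like sub-clusters 2 (336 cells) and 4 (202 cells) carried mnx1, isl1 and lhx4, factors of motor neuron identity. Cholinergic genes were found in 89.5% (85.4% to 92.7%) and 79.7% (73.0% to 85.3%) of their thinned cells. The leading genes of both held no fixed marker of this class, so the names rest on the raised markers. Library 1 gave 133 cells of sub-cluster 4. Sub-clusters 9 (155 cells) and 19 (59 cells) carried pkd2l1 and pkd1l2, channel genes of neurons that touch the cerebrospinal fluid, with pkd2l1 at 6255 CPM in 97.1% of the cells of sub-cluster 9, in 79.3% of those of sub-cluster 19 and in at most 11.8% of any other, and gad2 in 42.9% (34.5% to 51.5%). In sub-cluster 19 the dopamine-synthesis gene th was found in 63.8% of cells (at most 12.1% in any other sub-cluster) and the dopamine transporter gene slc6a3 in 43.1% (at most 2.17%), with GABAergic genes in 25.9% (15.3% to 39.0%). The leading genes of sub-cluster 19 held none of the fixed markers of its class, and included foxa2, a floor plate gene, and a2ml1 and col8a1, which were also leading genes of floor plate-like sub-cluster 15 of the progenitor-like cells, so its name is uncertain. The rule named sub-cluster 5 (200 cells) dI2-like and sub-cluster 13 (114 cells) dI4-like from lhx1 and lhx5, genes shared by several interneuron classes, with pou4f1 and pax2 respectively. Both had mainly glutamatergic genes (71.5%, 64.7% to 77.6%, and 68.3%, 58.4% to 77.1%) and also carried evx2, a factor of V0 interneurons, at 160.5 and 282 CPM. In sub-cluster 13, gad2, slc6a5 and slc32a1 were each found in 0 of the 104 thinned cells (upper limit 3.48%). Thinned to the same depth, slc32a1 was found in 32.1% of cells of sub-cluster 9, 28.8% of sub-cluster 10 and 22.4% of sub-clusters 8 and 19. These values argue against sub-cluster 13 being mainly inhibitory. At 1000 UMIs per cell they do not exclude single inhibitory cells in it. The leading genes of sub-clusters 5 and 13 held no fixed marker of their classes, so both names are uncertain. A sensory neuron-like sub-cluster, 23 (40 cells), had the touch channel gene piezo2 in 75% of cells, against at most 16.8% in any other.

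Unnamed sub-clusters carried known factors as well. Sub-cluster 1 (345 cells) had mnx1 at 530.1 CPM and chat at 940.1 CPM, with cholinergic genes in 78.8% (74.1% to 83.0%) of its cells. In sub-cluster 8 (160 cells) the glycine transporter gene slc6a5 was found in 30.8% of cells (23.3% to 39.0%) beside lhx1 at 578 CPM. All 47 cells of sub-cluster 22 came from library 1, with pax6 at 1205 CPM beside crx and vsx1, genes of retinal neurons. The leading genes of sub-clusters 3 (257 cells) and 24 (20 cells) were globin and myosin genes, which are not neuronal.

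**Figure D3:**
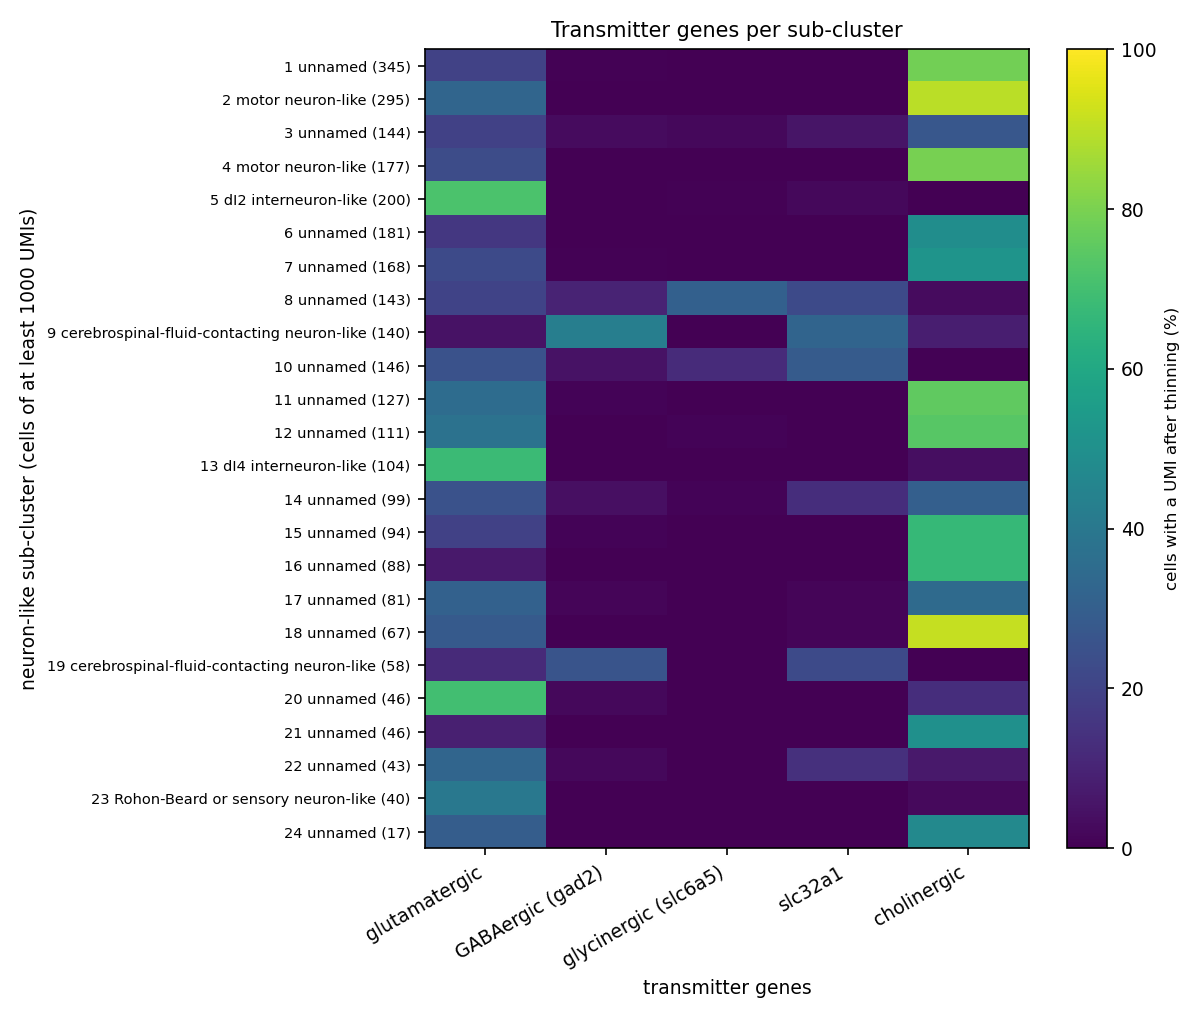
Percent of thinned cells with a UMI of each transmitter's genes (colour, 0 to 100) in each neuron-like sub-cluster (y axis, with the number of thinned cells) for 5 gene sets (x axis). Cholinergic genes reach 91.0% in sub-cluster 18, glutamatergic genes 71.5% in sub-cluster 5 and gad2 42.9% in sub-cluster 9.

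Among the progenitor-like cells, 17 sub-clusters were found, of which 4 could be named. Unnamed sub-clusters 3 (273 cells), 8 (179 cells) and 9 (172 cells) had globin, keratin or myosin genes, which are not neural, among their leading genes. Their median depths were 1794, 1418 and 1261 UMIs. Sub-cluster 3 also had neurog1 and neurod4 raised and the highest pax6 level of any sub-cluster, 460 CPM, and 201 of its cells came from library 1. Floor plate-like sub-cluster 15 (76 cells) carried shh, the ventral signal, with foxa2 and arx, and had pax6 at 13.3 CPM. Roof plate-like sub-clusters 6 (201 cells) and 7 (182 cells) carried msx1, rspo2 and wnt3a, dorsal midline genes, with pax6 at 28.3 and 68.4 CPM. Of sub-cluster 6, 173 cells came from library 7. Its leading genes held no fixed marker of its class, so its name rests on the raised markers. Precursor-like sub-cluster 5 (237 cells) carried neurog2 and dbx1, a gene of the V0 interneuron marker list, beside the progenitor genes hes5.3, hes5.4 and hes5.5. It had pax6 at 257 CPM and a pax6 UMI in 25.0% of thinned cells (19.6% to 31.0%). Its leading genes held more progenitor markers than precursor markers, and the progenitor class was not among the names on offer, so its name is uncertain.

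The comparisons of injured with uninjured tails at days 1, 3 and 7 and of mid-trunk with tail tip were not made. They need a record of which of the 8 libraries holds which sample, and none was found in the files or labels.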

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

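The lists of lens and photoreceptor genes and the tests of free RNA and of lens membrane genes were all chosen after the leading genes of the clusters had been seen. In library 1, lens genes stood at 6905 CPM in an unnamed cluster led by crystallin genes, a signal outside the classes compared above and far over the limit that a count of 0 allows. It came from 3645 UMIs, mainly of cryba4 (1961 CPM), cryba1 (1667 CPM), crybb1 (1135 CPM) and cryba2 (727 CPM), the structural proteins of the lens, and 13 of the cluster's 233 cells in that library had at least 3 of them. The other 6 libraries with cells in this cluster had 0 to 1.54 CPM there. Over all cells the lens genes stood at 140.4 CPM in library 1 and between 1.36 and 6.03 CPM elsewhere. Photoreceptor genes such as rcvrn (394 CPM) and sag (294 CPM) stood in a neuron-like cluster of 240 cells, in its 97 cells of library 1 at 1642 CPM together, from 246 UMIs, with 5 cells at 3 or more. The marker lists fixed for naming held no photoreceptor genes, so this cluster kept its name. Neuron-like cells of library 1 outside it had 55.1 CPM of these genes together. Pooled over libraries and without this cluster, progenitor-like and neuron-like cells had at most 3.20 CPM of a lens gene (cryba2) and 2.72 CPM of a photoreceptor gene (crx).

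Free RNA alone would put similar levels into every class of library 1. The lens level of the crystallin-led cluster was 288 times that of neuron-like cells, the highest of 4 other classes there (24.0060 CPM). That cluster was picked because crystallin genes led it, so a higher level was fixed in advance and free RNA is not excluded. The lowest of the 4 classes, skeletal muscle-like cells, had 6.18 CPM, against 1.36 to 6.03 CPM over all cells of the other libraries. Some free lens RNA in library 1 therefore remains open. Eye cells in the library are a candidate source that the values leave open. Neuron-like sub-cluster 22, 47 cells that all came from library 1, had the retinal genes crx and vsx1 among its leading genes. Of these cells, 42 lay outside the photoreceptor-led cluster, so leaving out that cluster kept them among the neuron-like cells. Of the 16 cells of library 1 with at least 3 crystallin UMIs, 68.8% (41.3% to 89.0%) also had a UMI of a lens membrane gene, against 1.04% of the other 3669 cells, but the membrane genes lim2 and mip had already been seen among the leading genes of the cluster, so this share restates the pattern and decides nothing. The sort would not remove such cells if they carried the pax6 reporter, since pax6 is also active in the eye. How eye cells could enter a sample of tail or trunk remains open, and no biological explanation was tested, because the library's sample is unknown.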

How the results depend on the processing

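Tests of gad1.1 and gad1.2, of 1 slc17a6 feature, of the photoreceptor-led cluster, of cells with at least 3000 UMIs and of other naming rules were chosen after seeing the data. A reversal was defined for log2 ratios only, and none was found. The 103 named genes kept their direction in all 2060 recomputed values and 14 list medians in all 280. Named genes had been picked for large folds, the 12 largest in each direction also for the same direction in every library. Their kept direction was therefore largely fixed in advance. Of 150 recomputed values of the main results, 109 stayed within the counting interval or within 1.5 times a gene count, and of 88 with a library left out, 66 did. Main results here are the neural, neuron-like, progenitor-like pax6, cycling and transmitter shares and the 2 gene counts, and no library's removal moved one by over 1.5 times. Other values did move. Without library 1 the pax6 ratio of progenitor-like to neuron-like cells rose to 25.8-fold, and the neuron-like pax6 share fell from 0.912% to 0.289%. Naming by markers against all other cells, or without a margin, changed no main result. For the values below the cause was not tested, except where stated. The neural share (24.5%) was 22.3% with at least 1000 genes, 22.0% at resolution 2.0, 21.8% with 4000 variable genes, 23.1% with 15 principal components, 29.3% as an unweighted mean over libraries, 23.8% without the photoreceptor-led cluster and 23.6% from 3000 UMIs, and 22.3% to 26.6% with a library left out. Neuron-like cells among neural cells (45.4%) were 49.8%, 50.5%, 50.5% and 39.99% under the former 4 settings in that order, 46.8% with doublets kept, 43.5% without the photoreceptor-led cluster, 43.7% from 3000 UMIs, and 42.0% to 49.3% with a library left out. The pax6 share of progenitor-like cells (9.94%) was 8.64% with at least 1000 genes and at resolution 2.0, 8.85% with 4000 variable genes and 8.33% to 11.1% with a library left out; a demand for 2 UMIs gave 1.67% and no thinning 33.6%, by construction. Cycling progenitor-like cells (51.6%) were 47.7% at resolution 0.5, 46.0% as an unweighted mean, 82.7% without thinning (55.6% in neuron-like and 74.3% in named non-neural cells) and 47.3% to 54.1% with a library left out. Without thinning, transmitter shares rose to 59.6% glutamatergic, 9.20% GABAergic, 5.05% glycinergic, 11.6% slc32a1 and 59.8% cholinergic, because more UMIs were read per cell. The unweighted mean gave 26.4% glutamatergic, 4.89% GABAergic and 48.8% cholinergic cells; 15 principal components gave 50% cholinergic cells. With 1 slc17a6 feature 26.0% were glutamatergic, with gad1.1 and gad1.2 7.43% were GABAergic, and from 3000 UMIs 1.73% were glycinergic. With a library left out the glutamatergic share was 26.6% to 29.2%, the GABAergic 2.92% to 4.19% and the cholinergic 43.8% to 48.5%. Of the genes 4-fold apart (841 toward progenitor-like and 793 toward neuron-like cells), a threshold of 50 CPM left 452 and 467, 2-fold gave 1405 and 1510, and 8-fold 522 and 513, by construction; with 4000 variable genes 497 were higher in neuron-like cells, where more genes had been set aside as clustering genes. Cells from 3000 UMIs gave 868 and 828 genes, of which 810 and 779 were shared with the reported ones. Scaling without the 20 highest genes was not run, because it belonged to the comparison of injured with uninjured tails, and counting floor and roof plate clusters as progenitor-like moved nothing, because no whole cluster bore those names. No paired analysis of the study's groups was possible because each group had 1 sample and the barcodes carried no sample. Progenitor-like and neuron-like cells share libraries, but the design fixed beforehand had no paired test for them, and they were compared within each library by direction only. Depth limits what a missing UMI shows, since a thinned cell has 1000 UMIs.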

Other observations

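The test of depth was set before its result was seen; the tests of lost cytoplasmic RNA, of UMIs per cell and of the gate were chosen after. Genes of the fixed lists differed widely between libraries within a class, with no condition known for any of them. In progenitor-like cells hmga2, a chromatin protein gene of growing tissue, ran from 7.86 CPM (3 UMIs, library 6) to 516 CPM (library 1) with a median of 104.6 CPM, and the cytokine gene il11 from 12.01 CPM (18 UMIs, library 4) to 556.7 CPM (library 5) with a median of 49.6 CPM. Fibronectin (fn1) ran from 42.6 CPM (library 1) to 502 CPM (library 3). The Wnt pathway gene lgr5 ran from 7.45 CPM (library 7) to 143 CPM (library 1), and fos, an immediate early gene, from 189.5 CPM (library 7) to 1153 CPM (library 1). In neuron-like cells the leptin gene lep had 0 CPM in libraries 3 and 4 and up to 110 CPM in library 5, with 103 CPM in library 7 and a median of 3.04 CPM. The injury-response factor gene atf3 ran from 14.4 CPM (library 4) to 267 CPM (library 7) with a median of 44.7 CPM, and the peptide gene calca from 13.9 CPM (library 1) to 333 CPM (library 7). For th the range was 4.399 CPM (library 4) to 249 CPM (library 6). The mix of clusters within a class also differed: the low-UMI progenitor-like cluster held 10 of 56 such cells in library 6 and 288 of 419 in library 3. A cluster with pkd2l1 and th among its leading genes held 15 of 59 neuron-like cells in library 6 and 32 of 415 in library 4. A cluster led by cyp3a5, tac1 and lepr had 137 of its 291 cells in library 5 and 147 in library 7. These ranges therefore do not separate a change within a cell type from a change in the mix.

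Some neural sub-clusters came mainly from a few libraries. Neuron-like sub-cluster 7 (168 cells), with cyp3a4.2, lep and asns, the asparagine synthetase gene, among the leading genes, held 84 cells of library 7 and 76 of library 5, with tac1 at 8471 CPM and cholinergic genes in 51.8% of cells (44.0% to 59.5%). Sub-cluster 15 (104 cells), led by il11, held 99 cells of library 5, and sub-cluster 17 (85 cells), in which lepr and il1r2 were leading genes, held 70 of library 7; its leading genes dock2 and skap2 were also those of an unnamed cluster with myeloid markers, and il1r2 that of a myeloid-like cluster. Among progenitor-like cells, all 41 cells of sub-cluster 16, with the chemokine gene cxcl8a.2 and il11 among the leading genes, came from library 5, as did 124 of 125 cells of sub-cluster 12, and all 40 of sub-cluster 17 came from library 2. Sub-clusters 11 and 13, with nkx2-2, a factor of ventral progenitors, among the leading genes, held 127 and 123 cells. Outside the nervous system, myeloid-like cells ran from 0.199% of library 4 to 15.2% of library 2, with a median of 2.87%.

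Several classes held a cluster of low and a cluster of high UMI count under the same name: progenitor-like clusters with medians of 1974 and 11613 UMIs, neuron-like with 2179 and 11378, and mesenchyme-like with 1739 and 13356. Depth alone would leave hardly any difference after thinning, but 10.6%, 15.7% and 24.1% of genes were 4-fold apart between the thinned clusters of a pair. These genes included the clustering genes that had set the clusters apart. Some difference was therefore fixed in advance, and depth as the reason for the split is not excluded. A loss of cytoplasmic RNA is a candidate explanation: ribosomal protein genes took 10.6%, 3.82% and 4.46% of UMIs in the low clusters against 26.6%, 15.3% and 24.8% in the high ones. Across genes, which are not independent replicates, the ratios of the 3 pairs had Spearman correlations of 0.911, 0.938 and 0.897. Median mitochondrial shares were higher in the low clusters (3.85% against 1.69%, 2.58% against 2.22%, and 4.35% against 2.06%), and no biological explanation was tested.

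Named non-neural cells, 56.4% of those used, had hardly any pax6 UMI although GFP under pax6 was sorted. Fewer UMIs per cell would not explain this: after thinning, progenitor-like cells still had a pax6 UMI 50.4 times as often (9.60% against 0.0958% from 3000 UMIs, and 8.64% against 0.305% at resolution 2.0), and before it the non-neural cells had the higher median (9000 UMIs against 5003). Autofluorescent cells in the gate, or GFP that outlasts pax6 transcripts or is made outside its domain, cannot be told apart, because 0 features of the matrix were named for a reporter. No biological explanation was tested.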
